A study of Capra hircus with 24 samples.

How the data were processed

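Papilla cells of cashmere goats, taken from the secondary or the primary type of hair follicle, were measured by RNA sequencing in 24 libraries, 3 for each combination of follicle type, month (June or October) and sex. Per the labels' protocols, total RNA was extracted with RNAiso Plus, a TRIzol-type reagent, and paired-end libraries were made with an NEBNext Ultra kit. Per the submitters' processing notes, kallisto 0.46.1, which assigns reads to transcripts without full alignment, and sleuth 0.30.0, which works on its estimates, were used, with no role or order given. The genome build, the transcript set, the filters and the sequencing depth are not given in the sources used here. The deposited values are a normalised expression signal with 2 decimals, 1 value per protein-coding gene and library, for 20326 genes with their symbols and NCBI gene IDs. They are not counts: library totals run from 959766 to 1045876 and their geometric mean is 1e+06, as TPM values divided by 1 factor per library would give, and no such factor is stated. Because the reads behind a value are unknown, no counting interval or detection limit is given, and precision rests on the spread between the 3 libraries of a group. Gene symbols are those of the deposited tables, and 20294 of the 20326 IDs matched the reference table of assembly ARS1.2, which served for names only, 20288 with the same symbol. Values of genes with close paralogs, such as keratins, depend on how the authors' software divided shared reads.

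Genes with a value of at least 1 in 3 or more libraries were kept, 13049 in all. Values were set to log2(value + 1) and fitted in limma 3.58.1 (R 4.3.3, statmod 1.5.0) with a mean for each of the 8 groups, a variance trend on mean expression and robust estimation, all 24 libraries sharing 1 estimate of the spread. A count-based test had been planned in case the values were counts, and the limma fit was the test planned for any other unit. There were 12 comparisons: secondary against primary cells in June and in October, October against June in secondary and in primary cells, the interaction of follicle type and month, males against females over all groups and in each of the 4 combinations of follicle type and month, and the interactions of sex with month and with follicle type. Comparisons of follicle type and month average the sexes with equal weight. They were also made within each sex, in the same fit of all 24 libraries and with its shared spread. Adjusted p-values are Benjamini-Hochberg values over the genes tested in a comparison, and a gene was called at an adjusted p under 0.05. The fit was tested on simulated data for secondary against primary cells in June (12611 genes): it recovered 45 of 50 genes changed 1.25-fold and 50 of 50 at each of 1.5-fold, 2-fold and 4-fold, called 7 of 12411 unchanged genes, and passed 0 of 30 random lists. The simulated noise was independent for each gene and library, with the spread found within groups, and the weakest genes were not among those changed. The simulation therefore does not cover groups that differ on their own, correlated genes, or recovery of weakly expressed genes.

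Gene lists, 34 in all, cover signalling and metabolic pathways, the matrix, the sex chromosomes, and markers of papilla cells and of the other cell types that a skin sample could hold. The 30 lists with at least 5 tested genes were tested with limma's camera with a preset correlation between genes of 0.01, again with a correlation estimated from the data, and with fry, with Benjamini-Hochberg adjustment over the lists of a comparison. Melanocyte, endothelial and pericyte markers had 4 tested genes each and got no list test. Their calls are given for secondary against primary cells in June, as counts with single genes named. The genes named in the text follow a rule: the 8 genes with the largest rise and fall in each of the 4 comparisons of follicle type or month, and 5 in the interaction of these factors and between the sexes, among called genes with a gene symbol and a mean of at least 5 in a compared group; up to 4 called members of a list, by p, where the list passed or had at least 3 calls; genes of the sex chromosomes; and 16 genes often studied in papilla cells. Of these 16, CORIN, FGF5, PRLR and MTNR1A did not reach the level for testing. Results of 2 genes that the rule names are not reported here. The tests, the lists, this rule and most alternatives were fixed before the data were examined. Alternatives were no filter, a filter of 1 in 6 libraries, a spread not estimated robustly, a fold of at least 2 as well, a pseudocount of 0.1, median-of-ratios factors, the compared groups alone, each library left out in turn, and the replicate number as a block. Rescaling each library to a common total of 1e+06, the comparisons within each sex as alternatives, and the 8 group means as single samples were added after the data were seen. Expected overlaps of call lists are those of independent lists of the same sizes. Principal components were computed from the 13049 tested genes.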

Results

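Dermal papilla cells are the mesenchymal cells at the base of a hair follicle, and they signal to the epithelial cells that form the hair. RNA of papilla cells from cashmere goats (Capra hircus) was sequenced. The cells belonged either to secondary follicles, which grow the fine cashmere fibre, or to primary follicles, which grow the coarse guard hair. Animals of both sexes were sampled in June, when the labels place the follicles in early anagen (the beginning of hair growth), and in October, when they place them in anagen (active growth). Follicle type, month and sex make 8 groups with 3 libraries in each, 24 libraries in all. The deposited values sum to between 959766 and 1045876 per library, and the number of reads behind them is unknown. Of the 20326 protein-coding genes listed, 13049 reached a value of 1 in at least 3 libraries and were tested. Across genes, which are not independent replicates, libraries of one group correlated with r from 0.993 to 0.997, and libraries of different groups with r from 0.954 to 0.992. The closest pair of groups was secondary October male and primary October male, with a mean r of 0.992. Mitochondrial transcripts made up 11.2 to 12.7% of the signal in the secondary October female libraries and 8.72 to 10.8% in the others. The labels call the libraries of a group biological replicates (bio rep) without saying whether they came from separate animals or cultures. Every p-value therefore measures only the spread between these libraries, which may still be partly technical. Fold changes are on the log2(value + 1) scale, which understates the change of weakly expressed genes, and a gene is called changed where its adjusted p (limma, Benjamini-Hochberg) is under 0.05. Statements on the highest and lowest genes cover those with a gene symbol and a mean value of at least 5 in a compared group.

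**Figure D1:**
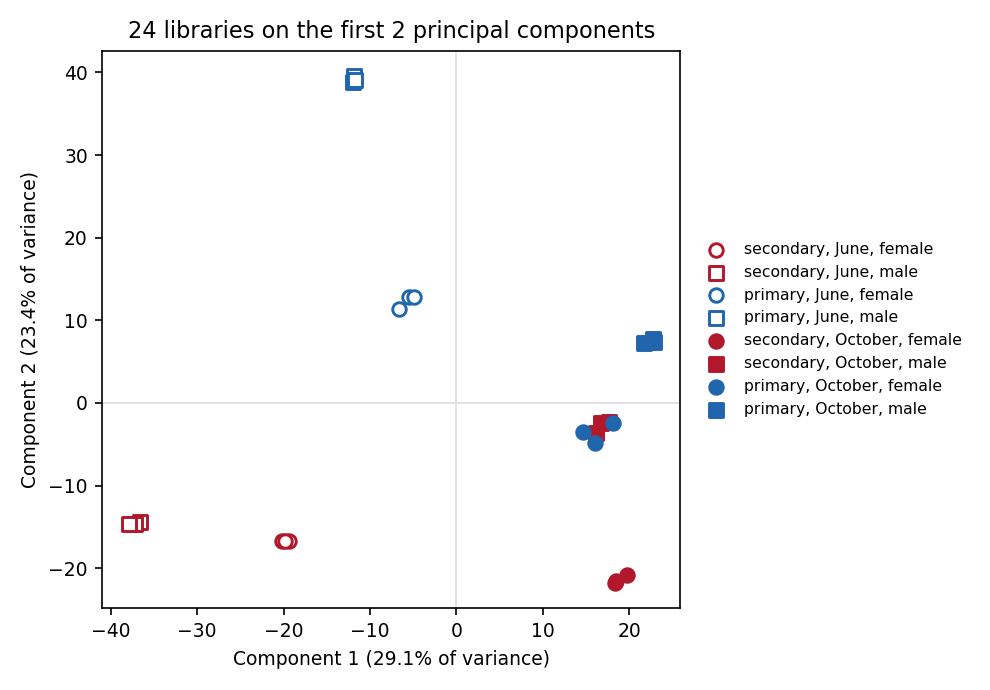
The 24 libraries on the first 2 principal components of log2(value + 1), which hold 29.1% (horizontal axis) and 23.4% (vertical axis) of the variance. Red marks secondary and blue primary follicles, open symbols June and filled symbols October, circles females and squares males. The 3 libraries of each group lie together, and the secondary October male libraries lie beside the primary October female ones on these axes.

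The first question is how papilla cells of the cashmere-growing follicle differ from those of the guard hair follicle, taken here in June and averaged over the sexes (6 libraries against 6). Cells of secondary follicles had higher levels of every one of the 49 tested cell cycle genes, and far lower levels of ALDH1A1, a retinaldehyde dehydrogenase that makes retinoic acid, and of SOX2, a transcription factor used as a papilla marker. ALDH1A1 (gene ID 102171605) differed by -4.13 (SE 0.067) on the log2 scale, with 2.75 ± 0.229 (SD, n = 3) in secondary females and 2.9 ± 0.428 in secondary males against 48.4 ± 1.44 and 89.1 ± 1.57 in primary females and males. SOX2 (gene ID 100861576) differed by -3.44 (SE 0.10), from 12.5 ± 1.74 and 12.7 ± 1.57 in primary females and males to 0.257 ± 0.176 and 0.26 ± 0.0361 in secondary ones. The largest difference in the other direction was that of LRRC15, a membrane protein of activated fibroblasts, at 3.04 (SE 0.034). In all, 8079 genes were called, 4130 higher and 3949 lower in secondary cells, and 560 of them differed by at least 2-fold.

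Other genes far higher in secondary than in primary cells in June were MMP3, a matrix metalloproteinase, at 2.95, TAC1, the precursor of substance P, at 2.75, and CMKLR1, the chemerin receptor, at 2.63. SCT, the secretin precursor, stood at 2.54 (SE 0.21) and THBD, thrombomodulin, at 2.47. Far lower, next to ALDH1A1 and SOX2, were IGF2, a growth factor, at -2.96, the ferritin receptor SCARA5 at -2.69, and PAPPA, a protease that releases insulin-like growth factors from their binding proteins, at -2.56. The alarmin IL33 differed by -2.53 and the uroplakin UPK1B by -2.43. Some of the largest differences were unequal in the sexes: the heat shock gene HSPA6 (mean 3.01) differed by 1.51 in females and 4.51 in males, the epidermal growth factor receptor ligand EREG (mean 2.60) by 0.84 in females and 4.36 in males, and the basal keratin KRT5 (mean -2.56) by -0.85 in females and -4.27 in males. Of genes often studied in papilla cells, FGF7 (-1.92), FGF10 (-0.85), ALPL (-0.63), IGF1 (-0.60) and RORA (-0.39) were lower in secondary cells, while WIF1 (0.79), BMP4 (0.16) and VCAN (0.11) were higher. RORA, a nuclear receptor of the circadian clock, went opposite ways in the sexes, at -1.09 in females and 0.31 in males. ALPL stood at -1.33 in females and 0.07 in males, and WIF1 at -0.30 and 1.87. LEF1 (0.05, adjusted p = 0.505) and NOG (-0.17, adjusted p = 0.147) were not called. Leaving out 1 library ended the call of VCAN without primary female 3 (0.09, adjusted p = 0.0543) or primary male 2 (0.09, adjusted p = 0.0524), and NOG was called without secondary male 1 (-0.24, adjusted p = 0.0321).

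Among the gene lists fixed in advance, cell cycle genes stood out in June: 49 of 49 were higher in secondary cells, 44 of them by at least 2-fold (median 1.51, adjusted p = 1.9e-34). The anaphase regulator CDC20 differed by 2.23 (SE 0.045), the spindle protein PRC1 by 2.07 (SE 0.041) and cyclin CCNB1 by 1.91 (SE 0.041). The proliferation marker MKI67 was at 18.2 ± 0.14 and 17.6 ± 0.884 (SD, n = 3) in secondary females and males against 5.53 ± 0.0702 and 3.55 ± 0.312 in primary ones. Of 29 cholesterol and lipid synthesis genes, 21 were higher and 2 lower (median 0.48, adjusted p = 5.14e-06, and adjusted p = 0.0786 with an estimated correlation), among them INSIG1, a sterol sensor partner, at 1.47, and HMGCS1, an early enzyme of the pathway, at 0.75. Oxidative phosphorylation had 27 of 42 higher and 2 lower (median 0.15, adjusted p = 0.00372, and adjusted p = 0.347 with an estimated correlation). The stress and unfolded protein response had 16 of 29 higher and 7 lower (median 0.18, adjusted p = 0.0421, and adjusted p = 0.347 with an estimated correlation). Growth factors and their receptors were lower, 25 of 35 against 7 higher (median -0.34, adjusted p = 0.000149), with the keratinocyte growth factor FGF7 at -1.92 (SE 0.061) and the binding protein IGFBP7 at -1.54. The senescence and p53 list had 14 of 20 lower and 4 higher (median -0.27, adjusted p = 0.0242, and adjusted p = 0.0786 with an estimated correlation). In it LMNB1, the lamin that is lost in senescent cells, differed by 1.36, and the cell cycle inhibitor CDKN1A by -0.47.

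Several structural lists were also lower in secondary cells in June. Of 25 collagens, 17 were lower and 6 higher (median -0.27, adjusted p = 0.00208, and adjusted p = 0.347 with an estimated correlation), among them COL3A1 at -1.15, COL5A2 at -0.90 and COL1A2 at -0.69. Dermal sheath and smooth muscle markers had 11 of 14 lower and 2 higher (median -0.39, adjusted p = 0.00112, and adjusted p = 0.128 with an estimated correlation), with the myosin light chain kinase MYLK at -1.56, the smooth muscle actin ACTG2 at -1.33, and SYNPO2 the other way at 1.14. Immediate early genes, which respond within minutes to growth factors and stress, had 16 of 26 lower and 4 higher (median -0.33, adjusted p = 0.000881, and adjusted p = 0.286 with an estimated correlation). FOS differed by -1.69 and FOSB by -2.25, and the list had a median of -0.65 in females and 0.02 in males. Keratinocyte and hair matrix markers, which mark epithelial cells, had 11 of 14 lower and 3 higher (median -0.40, adjusted p = 0.00415, and adjusted p = 0.121 with an estimated correlation). Their median was -0.03 in females and -0.67 in males. The papilla signature itself did not pass, with 6 of 18 higher and 9 lower (median -0.17, adjusted p = 0.318). Nor did Wnt ligands and receptors (7 higher, 14 lower of 27, median -0.15, adjusted p = 0.114) or BMP and TGF-beta signalling (15 higher, 17 lower of 34, median -0.18, adjusted p = 0.364). Single members moved far all the same: the Wnt inhibitors SFRP1 and DKK3 differed by -1.86 and -1.25, and ID1, a target of BMP signals, by 1.78. Adjusted over the list alone, cholesterol genes had 21 and 3 and immediate early genes 4 and 17 members higher and lower, and the other lists named for June kept their counts.

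Within the sexes, 6435 genes were called between secondary and primary cells in June in females and 7779 in males: 3613 changed the same way in both, where independent lists would share 1919, and 896 went opposite ways. With the 8 group means taken as single samples, which counts each group as 1 sample, 341 of the 8079 genes were called (263 higher, 78 lower), among them LRRC15, CDC20, CCNB1, SFRP1, DKK3, PAPPA and IGFBP7. ALDH1A1 (adjusted p = 0.0545) and SOX2 (adjusted p = 0.12) were not called in this fit.

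**Figure D2:**
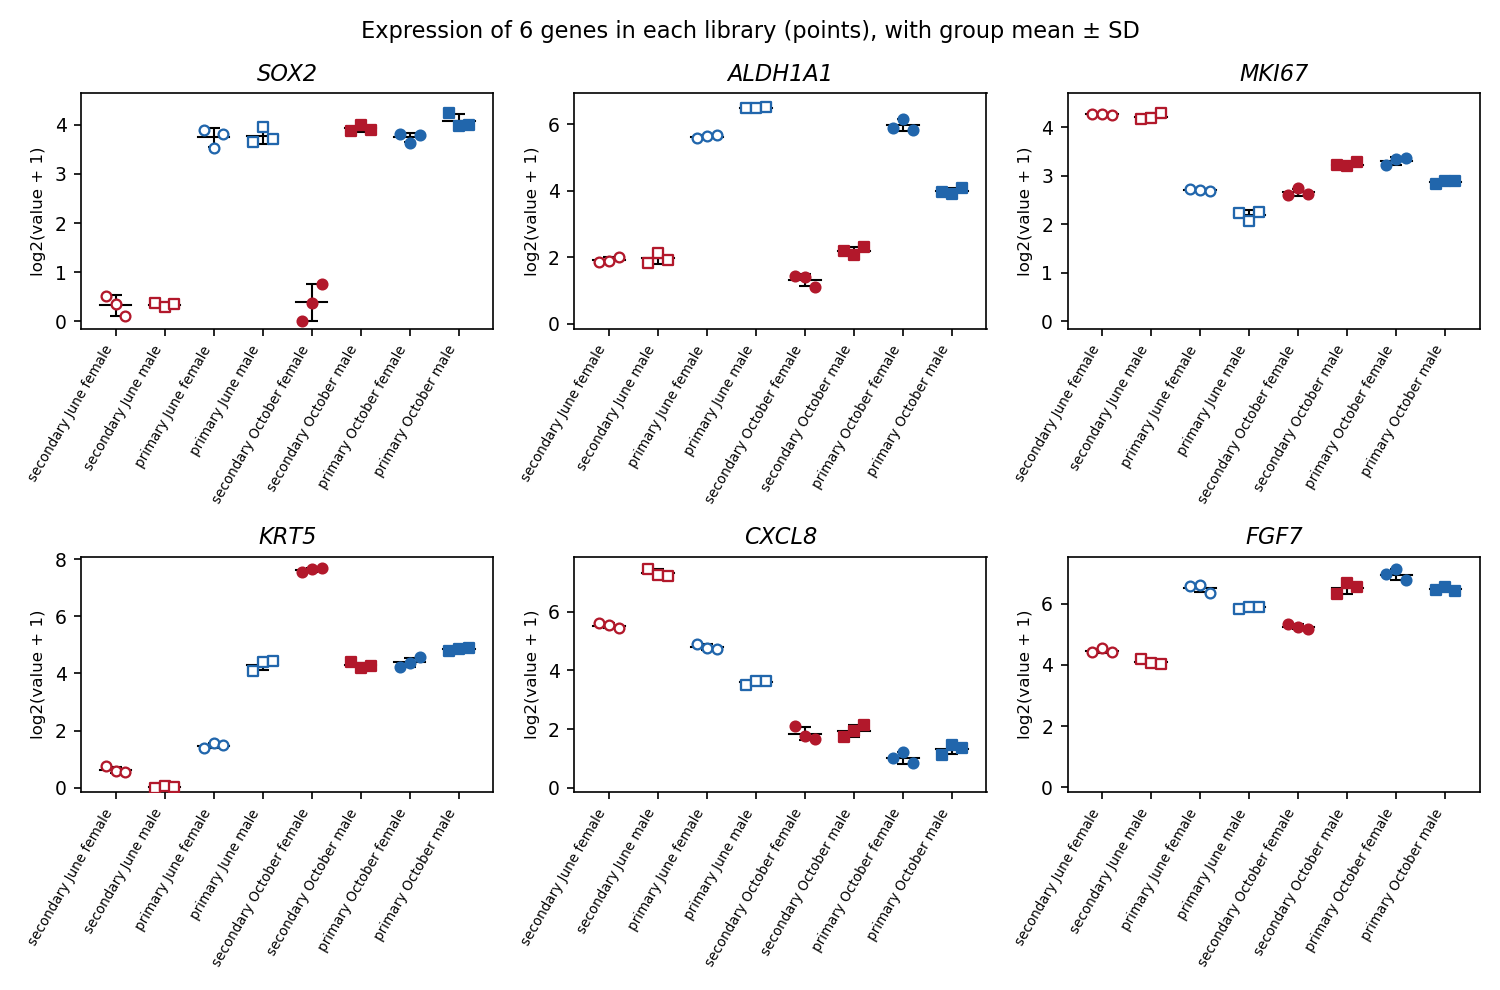
Expression of 6 genes in each of the 24 libraries as log2(value + 1) on the vertical axis, by group on the horizontal axis. Points are libraries, with colours and symbols for follicle type, month and sex as in the plot of principal components, and black lines are group means ± SD (n = 3). SOX2 lies near the bottom of its axis in 3 of the 4 secondary groups and at the primary level in secondary October males.

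The same comparison in October, in active growth, called fewer genes: 4116, of which 2282 were higher and 1834 lower in secondary cells, and 97 differed by at least 2-fold. ALDH1A1 was again the gene with the lowest value over 6 libraries against 6, at -3.22 (SE 0.067), with 1.51 ± 0.305 and 3.55 ± 0.391 (SD, n = 3) in secondary females and males against 61.7 ± 7.84 and 14.8 ± 0.986 in primary ones. SOX2 differed by -1.76 (SE 0.10) on average. It was lower in females (-3.36) and not called in males (-0.15), where secondary cells stood at 14.2 ± 0.738 and primary cells at 15.9 ± 1.73, and the sexes differed in this (adjusted p = 2.03e-11). The highest genes were GPNMB, a membrane glycoprotein, at 2.52 (SE 0.051), the matrix protein TNN (tenascin N) at 2.36 (SE 0.066), the serine hydroxymethyltransferase SHMT1 at 2.15 and DPT, a dermal matrix protein, at 2.15. LRRC15 was higher in this month too, at 1.65.

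Other low genes of October were UPK1B at -1.59, CLIC5 at -1.57 and PDK4, a kinase that limits glucose oxidation, at -1.51. CCL17 (-1.44) and DMRT2 (-1.41) were lower in the mean of the sexes but not in males alone. The intermediate filament gene DES (1.86), PPP1R1A (1.82) and GLDN (1.62) were higher. Among the often-studied genes VCAN (0.85), NOG (0.49) and ALPL (0.36) were higher, and BMP4 (-1.0), RORA (-0.23) and FGF7 (-0.83) were lower, FGF7 in females (-1.70) and not in males (0.04). ALPL stood at 0.77 in females and -0.05 in males. LEF1 (-0.10, adjusted p = 0.181), WIF1 (-0.22, 0.0627), FGF10 (-0.08, 0.316) and IGF1 (-0.09, 0.312) were not called. Leaving out 1 library, LEF1 was called without primary male 1 (-0.15, adjusted p = 0.0429). WIF1 was called without secondary female 2 (-0.28, adjusted p = 0.0241), secondary male 1 (-0.28, adjusted p = 0.0224) or primary female 3 (-0.26, adjusted p = 0.0454). Of the genes called in June, 2291 were called the same way in October (1219 higher and 1072 lower, where independent lists would share 722 and 555), and 711 the opposite way, where 1271 would be found.

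Epithelial markers were higher in secondary cells in October: 10 of 14 keratinocyte and hair matrix markers were called higher and 1 lower (median 0.48, adjusted p = 8.63e-06), with a median of 1.51 in females and -0.26 in males. KRT5 (gene ID 102175207) differed by 3.24 in females and -0.57 in males, its mean being 197 ± 9.45 (SD, n = 3) in secondary females and 18.5, 20.0 and 27.9 in secondary males, primary females and primary males. The mitochondrial share was also highest in secondary females, at 11.2 to 12.7% against 9.37 to 10.8% in the other October groups. Of 26 immediate early genes, 19 were higher and 3 lower (median 0.28, adjusted p = 1.11e-07, and adjusted p = 0.0776 with an estimated correlation), with FOS at 0.88 and EGR1 at 0.49 (0.99 in females, -0.01 in males). The interferon response had 18 of 31 lower and 1 higher (median -0.18, adjusted p = 8.15e-06), such as the antiviral gene MX1 at -0.78 and the RNA sensor IFIH1 at -0.56. Its median was -0.42 in females and 0.06 in males. Cholesterol and lipid synthesis had 17 of 29 higher and 2 lower (median 0.17, adjusted p = 2.28e-05, and adjusted p = 0.0776 with an estimated correlation), with a median of -0.02 in females and 0.34 in males. The HOX genes had 5 of 22 lower and 1 higher (median -0.08, adjusted p = 0.02, and adjusted p = 0.0727 with an estimated correlation), HOXB6 at -0.80 and HOXB7 at -0.69 among them. The cell cycle list, uniform in June, did not pass (1 higher and 7 lower of 49, median -0.05, adjusted p = 0.182), and its median was -0.29 in females and 0.23 in males.

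Matrix genes were mostly higher in secondary cells in October. Of 30 matrix proteases and inhibitors, 20 were higher and 4 lower (median 0.19, adjusted p = 2.84e-05), with ADAM12 at 0.41 and, the other way, TIMP3, an inhibitor of metalloproteinases, at -0.83. Collagens had 16 of 25 higher and 3 lower (median 0.16, adjusted p = 0.00178, and adjusted p = 0.322 with an estimated correlation), including COL7A1 at 1.16 and COL12A1 at 0.60. Other matrix proteins had 22 of 46 higher and 11 lower (median 0.10, adjusted p = 0.0139, and adjusted p = 0.322 with an estimated correlation). Markers of interfollicular fibroblasts had 7 of 10 higher and 2 lower (median 0.17, adjusted p = 0.00487), with the proteoglycans LUM and DCN at 1.2 and 0.79, and FBLN1 the other way at -0.91 (-1.89 in females, 0.07 in males). Oxidative phosphorylation had 10 of 42 higher and 0 lower (median 0.07, adjusted p = 0.0374, and adjusted p = 0.489 with an estimated correlation), with medians of 0.01 in females and 0.11 in males. The cytosolic ribosome had 0 of 73 higher and 9 lower (median -0.03, adjusted p = 0.032, and adjusted p = 0.644 with an estimated correlation), with medians of -0.16 in females and 0.09 in males. Adjusted over the list alone, the higher and lower members numbered 11 and 1 for keratinocyte markers, 20 and 2 for cholesterol genes, 21 and 4 for proteases, 25 and 12 for other matrix proteins, 0 and 4 for the ribosome and 1 and 6 for the cell cycle, and the remaining lists named for October kept their counts. With each library rescaled to a common total, 1649 genes were higher and 2693 lower in secondary cells, and the medians were 0.03 for oxidative phosphorylation, -0.08 for the ribosome, 0.07 for other matrix proteins and -0.12 for the HOX genes. Within the sexes, 4628 genes were called in females and 2412 in males, 881 the same way in both (430 from independent lists) and 499 opposite ways. With the 8 group means as single samples limma called 0 genes, with 446 at an unadjusted p under 0.05. These 446 are a share under 0.05 of the 13049 tested genes, no more than unchanged genes would give.

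**Figure D3:**
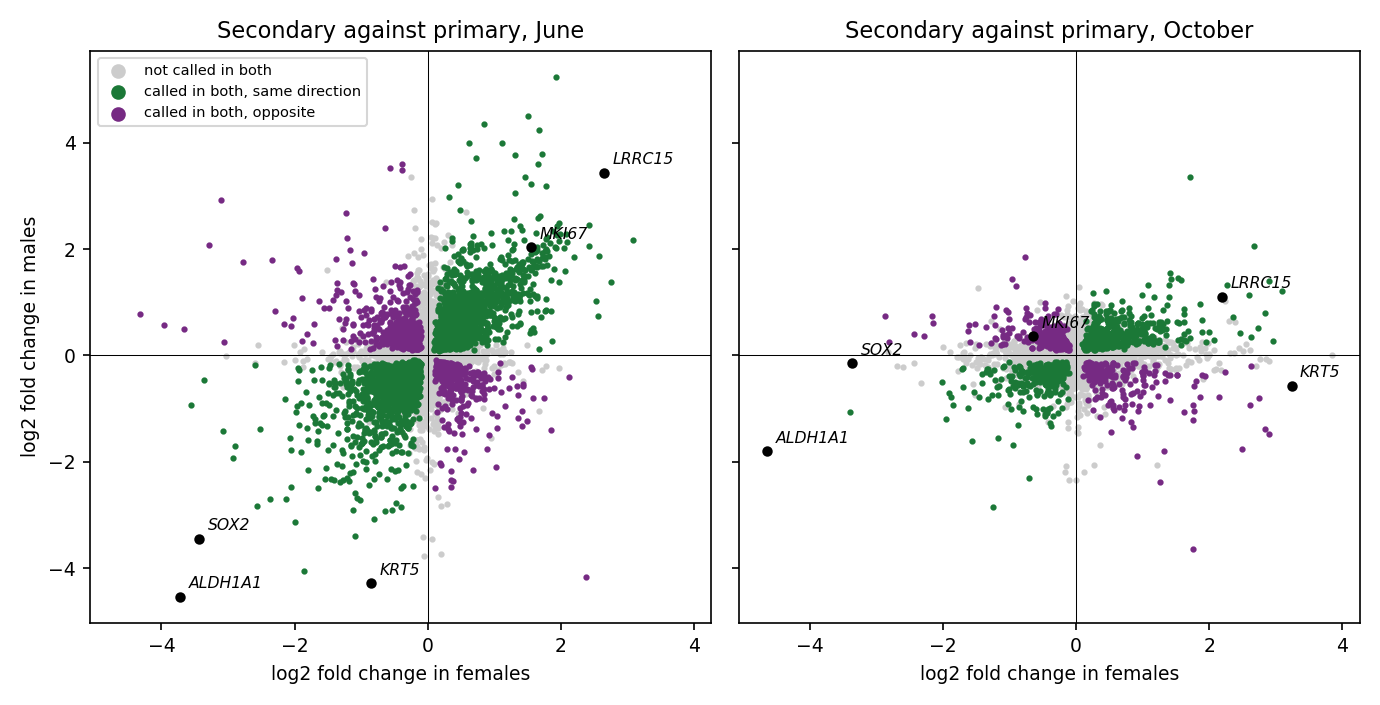
Difference between secondary and primary cells of each of the 13049 tested genes as log2 fold change in females (horizontal axis) and in males (vertical axis), in June on the left and October on the right. Green points were called in both sexes in the same direction (3613 in June, 881 in October), purple points in opposite directions (896 and 499), grey points were not called in both, and black points are 5 named genes.

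The next question is how papilla cells differ between June, labelled early anagen, and October, labelled anagen, first in the secondary follicle (October against June, 6 libraries against 6). Growth stage goes with the month here, so stage, season and any difference in how the cells were collected cannot be told apart. Epithelial keratins rose most and the chemokine CXCL8 fell most, and the cell cycle genes fell. KRT5 rose by 5.62 (SE 0.063), from 0.55 ± 0.114 and 0.0233 ± 0.0252 (SD, n = 3) in June females and males to 197 ± 9.45 and 18.5 ± 1.29 in October, and KRT14 by 4.51 (SE 0.067). CXCL8 (gene ID 102178438), which attracts neutrophils, changed by -4.54 (SE 0.082), from 45.2 ± 2.33 and 159 ± 14.6 to 2.61 ± 0.571 and 2.85 ± 0.525. Of 8206 genes called, 3788 rose and 4418 fell, 485 by at least 2-fold.

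Other large rises in secondary cells were those of DES (3.24), the gap junction gene GJB2 (3.16), the keratins KRT19, KRT6A and KRT8 (3.48, 3.29 and 2.90) and SERPINF1 (2.71), which encodes an inhibitor of blood vessel growth. Large falls were those of the protease inhibitor SERPINE2 (-2.99), EREG (-2.73), the neuropeptide gene NMU (-2.71), COL8A1 (-2.52), CPXM1 (-2.50), ID1 (-2.37) and the cation channel TRPC4 (-2.26). The Wnt inhibitors SFRP1 and SFRP2 rose by 1.96 and 1.71, as did the Wnt target AXIN2 (1.38) and IL33 (2.30). FGF7 rose by 1.60 (SE 0.061), and VCAN (0.42), FGF10 (0.30) and ALPL (0.24) rose less, while WIF1 (-1.41), BMP4 (-0.68), RORA (-0.48) and LEF1 (-0.36) fell. The rise of FGF7 was larger in males, from 15.33 to 17.27 in the June libraries to 78.44 to 100.81 in the October ones. In females FGF7 went from 20.15 to 22.21 in June to 35.15 to 39.45 in October. SOX2 (1.83) and IGF1 (1.07) rose on average, with SOX2 at 0.06 in females and 3.59 in males and IGF1 at -0.22 in females and 2.35 in males, neither of them called in females. ALPL changed by 0.53 in females and -0.05 in males, and RORA by 0.13 and -1.09. NOG (-0.15, adjusted p = 0.196) was not called.

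Of 49 cell cycle genes, 48 fell and 1 rose in secondary cells (median -0.99, adjusted p = 1.51e-20), 24 of them by at least 2-fold, MKI67 by -1.30 (SE 0.043) and CCNB1 by -1.15 (SE 0.041). Keratinocyte and hair matrix markers rose, 13 of 14 against 1 that fell (median 1.3, adjusted p = 3.99e-09), with a median of 2.50 in females and 0.54 in males. The mitochondrial share went from 8.89 to 9.45% in June females to 11.2 to 12.7% in October females. The interferon response fell, 25 of 31 against 1 (median -0.52, adjusted p = 4.54e-07), with MX1 at -1.35, SAMD9 at -1.36 and IFI44L at -1.22. Cholesterol and lipid synthesis had 19 of 29 up and 4 down (median 0.27, adjusted p = 0.000422, and adjusted p = 0.167 with an estimated correlation), DHCR7, the last enzyme of cholesterol synthesis, at 0.69. Collagens had 14 of 25 up and 6 down (median 0.29, adjusted p = 0.00441, and adjusted p = 0.294 with an estimated correlation), with COL3A1 at 1.33 and COL14A1 at 1.39, and their median was 0.06 in females and 0.43 in males. Other matrix proteins had 28 of 46 up and 13 down (median 0.23, adjusted p = 0.00356, and adjusted p = 0.268 with an estimated correlation), with periostin (POSTN) at 1.75 and the crosslinking enzyme LOX at 1.35. Ribosomal protein genes had 28 of 73 up and 6 down (median 0.07, adjusted p = 0.0332, and adjusted p = 0.599 with an estimated correlation), their median being -0.19 in females and 0.33 in males. Notch signalling fell (10 of 15 down, 1 up, median -0.30, adjusted p = 0.0407, and adjusted p = 0.176 with an estimated correlation), with the ligand JAG1 at -0.80. So did the senescence and p53 list (12 of 20 down, 4 up, median -0.29, adjusted p = 0.0486, and adjusted p = 0.127 with an estimated correlation). Dermal sheath and smooth muscle markers did not pass, and their median (-0.06) and test (upward, adjusted p = 0.303) had opposite signs. Adjusted over the list alone, 27 and 5 ribosomal genes were up and down, and the other lists named for secondary cells kept their counts. The ribosomal median was 0.04 with each library rescaled to a common total.

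In secondary cells, 3714 genes changed the same way between the months in females and in males (1905 from independent lists) and 814 opposite ways, of 6699 and 7378 called. With the 8 group means as single samples, 8 of the 8206 genes were called, among them SFRP1, IL33 and ID3, whose product is a target of BMP signals and which fell (-1.91).

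In the primary follicle the same months gave 7942 called genes, 3726 up and 4216 down in October, 343 by at least 2-fold. Here the cell cycle genes rose: 49 of 49 were higher in October (median 0.65, adjusted p = 2.13e-23), such as CDC20 at 1.04 (SE 0.045) and the replication helicase subunit MCM4 at 0.76 (SE 0.040), over 6 libraries against 6. Immediate early genes fell, 24 of 26 and none up (median -0.67, adjusted p = 3.8e-12), with FOS at -2.00 (SE 0.030) and EGR1 at -1.27 (SE 0.032); the list's median was -1.38 in females and -0.08 in males. Of single genes, KRT14 (2.47, SE 0.067) and KRT8 (2.21) rose most and CXCL8 (-3.04, SE 0.082) fell most.

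Further rises in primary cells were those of LIPG, an endothelial lipase, at 2.21, SERPINF1 at 1.88, CNGA3 at 1.83, KRT5 at 1.73 and LRRC15 at 1.72. The rise of KRT5 was mostly that of females, from 1.61 to 1.94 in the June libraries to 17.88 to 22.52 in the October ones. In males it went from 15.86 to 20.58 in June to 26.68 to 28.86 in October. Further falls were those of the neuritin gene NRN1 (-2.73), COL8A1 (-2.66), ID4 (-2.58), GPNMB (-2.38), the integrin ITGA4 (-2.34) and the angiotensin receptor AGTR1 (-2.28). ALDH1A1 changed by 0.34 in females and -2.52 in males, and its mean over the sexes fell (-1.09). FGF7 (0.52) and BMP4 (0.48) rose, while NOG (-0.81), ALPL (-0.75), RORA (-0.65), FGF10 (-0.47), VCAN (-0.33) and LEF1 (-0.21) fell. IGF1 changed by -0.80 in females and 1.91 in males, and WIF1, an inhibitor of Wnt signals, by -1.50 in females and 0.70 in males. ALPL changed by -1.58 in females and 0.07 in males, and LEF1 by 0.06 and -0.47. SOX2 was not called (0.15, adjusted p = 0.209).

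Among the other lists in primary cells, cholesterol and lipid synthesis rose, 24 of 29 against 4 (median 0.49, adjusted p = 3.99e-09), with HMGCS1 at 1.06 and the desaturase SCD at 1.24. Keratinocyte markers rose (12 of 14 up, 2 down, median 0.37, adjusted p = 0.000129). So did the cytosolic ribosome (33 of 73 up, 2 down, median 0.08, adjusted p = 0.000988, and adjusted p = 0.556 with an estimated correlation), with medians of 0.02 in females and 0.18 in males. Markers of interfollicular fibroblasts had 5 of 10 up and 1 down over both sexes (median 0.10, adjusted p = 0.025, and adjusted p = 0.0588 with an estimated correlation), but their median was -0.09 in females and 0.23 in males. BMP and TGF-beta signalling fell, 23 of 34 against 7 (median -0.27, adjusted p = 0.000118), with ID3 at -1.93 and ID1 at -1.33. Inflammation and NF-kB genes had 16 of 24 down and 4 up (median -0.25, adjusted p = 0.00114), including the inhibitor NFKBIA (-1.60) and the cytokine IL1A (-2.06). The senescence and p53 list had 13 of 20 down and 2 up (median -0.23, adjusted p = 0.00454), with the stress cytokine GDF15 at -1.95 and CDKN1A at -0.78. The papilla signature had 12 of 18 down and 3 up (median -0.33, adjusted p = 0.025, and adjusted p = 0.139 with an estimated correlation), RSPO3, which strengthens Wnt signals, at -0.66 among them. The circadian clock and seasonal hormone receptor list had 13 of 19 down and 6 up (median -0.37, adjusted p = 0.025, and adjusted p = 0.0588 with an estimated correlation), with the repressor NFIL3 at -0.91. Dermal sheath markers had 9 of 14 down and 2 up over both sexes (median -0.25, adjusted p = 0.0218, and adjusted p = 0.183 with an estimated correlation), with a median of 0.06 in females and -0.54 in males. The interferon response had 18 of 31 down and 2 up (median -0.19, adjusted p = 0.025, and adjusted p = 0.139 with an estimated correlation), with a median of 0.01 in females and -0.37 in males. Notch signalling fell (9 of 15 down, 1 up, median -0.26, adjusted p = 0.025, and adjusted p = 0.112 with an estimated correlation). Adjusted over the list alone, the ribosome had 30 and 1 and the senescence list 2 and 14 members up and down, and the other lists named for primary cells kept their counts.

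With each library rescaled to a common total, 4662 genes rose and 3464 fell in primary cells, and the medians were 0.16 for interfollicular fibroblast markers and 0.14 for the ribosome. Between the sexes, 3434 genes changed the same way (1753 from independent lists) and 794 opposite ways. With the 8 group means as single samples limma called 0 genes, with 2589 at an unadjusted p under 0.05. Over the follicle types, 4421 genes changed the same way between the months, 1864 up (1082 from independent lists) and 2557 down (1427), and 1203 opposite ways (2485).

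Whether the change from June to October differs between the follicle types was tested as the interaction of follicle type and month, in which a positive value means a larger rise, or a smaller fall, in secondary cells. The cell cycle list was uniform: 49 of 49 genes had a negative interaction (median -1.56, adjusted p = 7.05e-46), with CDC20 at -2.25 (SE 0.064), PRC1 at -2.08 (SE 0.058) and MKI67 at -1.94 (SE 0.060) over the 24 libraries. KRT5 (3.89, SE 0.088), DES (3.73), FOSB (3.23), GJB2 (2.85) and the water channel AQP1 (2.81) had the largest positive values, and EREG (-3.01, SE 0.12), HSPA6 (-2.84), SCT (-2.64) and MMP3 (-2.32) the lowest. In all, 6023 genes had an interaction, 3041 positive and 2982 negative, 477 of at least 2-fold. With each library rescaled to a common total, 2090 were positive and 4267 negative.

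Wnt ligands and receptors had 18 of 27 positive and 2 negative (median 0.27, adjusted p = 0.000809), among them the ligand WNT2 at 1.60 and the receptor ROR2 at 0.72, and a list median of 0.41 in females and 0.05 in males. Wnt targets and inhibitors had 6 of 16 positive and 3 negative (median 0.19, adjusted p = 0.0207), the inhibitors SFRP2 and SFRP1 at 2.08 and 1.59. Growth factors and receptors had 23 of 35 positive and 8 negative (median 0.36, adjusted p = 0.000852), with IGFBP3 at 1.58 and FGF7 at 1.08. The rise of FGF7 in secondary cells was larger in males than in females, as given above. BMP and TGF-beta signalling had 20 of 34 positive and 8 negative (median 0.27, adjusted p = 0.0192), with the activin subunit INHBA at 1.71. Immediate early genes had 21 of 26 positive and 2 negative (median 0.49, adjusted p = 1.88e-09), with a median of 0.96 in females and 0.07 in males. Inflammation and NF-kB genes had 11 of 24 positive and 4 negative (median 0.10, adjusted p = 0.0335, and adjusted p = 0.0547 with an estimated correlation), including PTGS2, the inducible cyclooxygenase, at 1.64. Their median was 0.49 in females and -0.21 in males. The papilla signature had 12 of 18 positive and 4 negative (median 0.51, adjusted p = 0.00545, and adjusted p = 0.0828 with an estimated correlation), with SOX2 at 1.68 and VCAN at 0.75. The value of SOX2 came from males. In the secondary October libraries SOX2 stood at 0 to 0.7 in females and 13.72 to 15.07 in males. It stood at 0.07 to 0.42 in the secondary June libraries and 10.58 to 17.9 in all primary ones.

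Keratinocyte markers had 12 of 14 positive and 1 negative interactions (median 0.86, adjusted p = 5.8e-07). Collagens had 17 of 25 positive and 4 negative (median 0.44, adjusted p = 2.25e-06, and adjusted p = 0.113 with an estimated correlation), with COL3A1 at 1.02. Other matrix proteins had 24 of 46 and 13 (median 0.19, adjusted p = 0.00712, and adjusted p = 0.26 with an estimated correlation), with the laminin LAMA2 at 2.17. Dermal sheath markers had 8 of 14 and 1 (median 0.19, adjusted p = 0.000772, and adjusted p = 0.0828 with an estimated correlation), with medians of -0.23 in females and 0.74 in males. The interferon response had negative interactions (1 positive, 17 negative of 31, median -0.27, adjusted p = 0.000161), with MX1 at -1.25. Cholesterol and lipid synthesis had them too (4 positive, 19 negative of 29, median -0.34, adjusted p = 0.000652, and adjusted p = 0.113 with an estimated correlation), with INSIG1 at -1.22. Adjusted over the list alone, positive and negative members numbered 21 and 3 for immediate early genes, 1 and 20 for the interferon response, 7 and 4 for Wnt targets and 11 and 5 for inflammation, and the other lists named for the interaction kept their counts. Rescaling moved the median of dermal sheath markers to 0.11 and that of inflammation to 0.02. With the 8 group means as single samples limma called 0 interactions, with 1181 genes at an unadjusted p under 0.05.

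**Figure D4:**
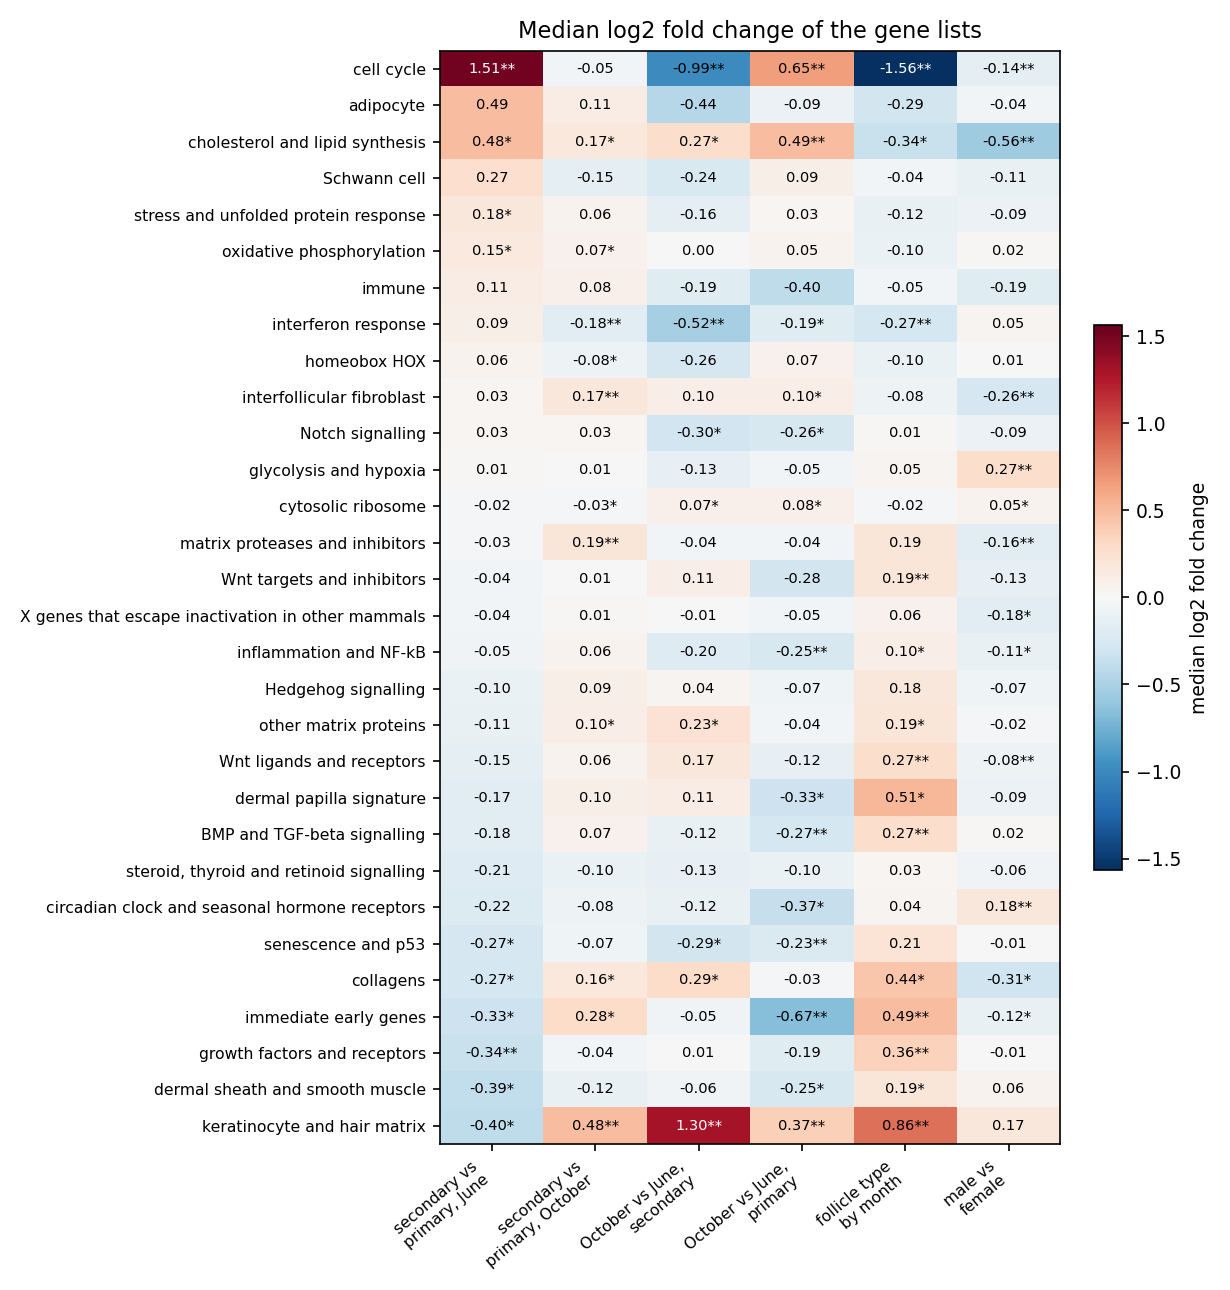
Median log2 fold change (number and colour) of the tested members of 30 gene lists, in lines, for the 6 comparisons, in columns. One asterisk marks a list that passed the camera test with the preset correlation (adjusted p under 0.05) and 2 asterisks one that also passed with an estimated correlation. The median of the cell cycle list was 1.51 between secondary and primary cells in June, -0.99 from June to October in secondary cells and 0.65 in primary cells.

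The last comparison sets males against females, over all follicle types and months (12 libraries against 12). SRY, from the fixed list of Y-linked genes, was listed at 0 in all 24 libraries. Of 10 X-linked genes that escape inactivation in other mammals, 6 were lower in males and 1 higher (median -0.18, adjusted p = 0.00267, and adjusted p = 0.0641 with an estimated correlation), with EIF2S3 at -0.73 (SE 0.029) and KDM6A at -0.63 (SE 0.034). Males had lower levels of the Wnt ligand WNT5A (-1.22, SE 0.020), in each of the 4 cell groups. It stood at 75.2 against 160.2 in secondary June, 61.4 against 149 in primary June, 72.4 against 195 in secondary October and 59.8 against 131 in primary October. TNN (-2.00, SE 0.046) and the fatty acid desaturase FADS2 (-1.88, SE 0.053) were lower in males in each of the 4 cell groups as well. Of 6523 genes called, 3324 were higher and 3199 lower in males, 114 by at least 2-fold.

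The genes furthest up in males were DES (1.99, SE 0.038), the glucose transporter SLC2A3 (1.73), SPARCL1 (1.66), FAM198B (1.54) and IGF2 (1.5). Those furthest down next to TNN and FADS2 were AQP1 (-2.23, SE 0.039), LAPTM5 (-1.87) and C1QTNF3 (-1.84). LAPTM5, a lysosomal protein of blood cells, was lower in the males of primary follicles (-4.72 in June, -3.02 in October) but not in those of secondary ones (0.38 and -0.13). Cholesterol and lipid synthesis was lower in males, 28 of 29 genes and none higher (median -0.56, adjusted p = 2.18e-22), with SCD at -1.32 (SE 0.033) and the epoxidase SQLE at -0.80 (SE 0.026). Glycolysis and hypoxia genes were higher, 31 of 35 against 2 (median 0.27, adjusted p = 1.67e-13), including BNIP3 (0.76) and the carbonic anhydrase CA12 (0.62), although their median was -0.04 in primary June. Cell cycle genes were lower on average, 34 of 49 and none higher (median -0.14, adjusted p = 1.36e-06), with the nucleotide reductase subunit RRM2 at -0.34. Their median was -0.10 in secondary June and -0.36 in primary June and in primary October, and they were higher in males in secondary October (24 higher, 3 lower, median 0.19, adjusted p = 0.00126). Matrix proteases and inhibitors were lower on average (18 of 30 lower, 6 higher, median -0.16, adjusted p = 0.000109) but had a median of 0.06 in secondary June, where MMP2 (-0.52 on average) stood at 0.37. Lower averages were also found for Wnt ligands and receptors (14 of 27 lower, 4 higher, median -0.08, adjusted p = 0.0115) and interfollicular fibroblast markers (6 of 10 lower, 2 higher, median -0.26, adjusted p = 0.00986), with medians the other way in primary October (0.10) and secondary June (0.11), respectively. Collagens were lower as well (18 of 25 lower, 5 higher, median -0.31, adjusted p = 3.45e-06, and adjusted p = 0.143 with an estimated correlation), with COL18A1 at -1.12, though at 0.70 in primary October. Immediate early genes had 15 of 26 lower and 4 higher (median -0.12, adjusted p = 0.00238, and adjusted p = 0.297 with an estimated correlation), with medians of -0.66 in primary June and 0.11 in primary October. Inflammation had 11 of 24 lower and 6 higher (median -0.11, adjusted p = 0.0349, and adjusted p = 0.0561 with an estimated correlation). Its genes were higher in males in secondary June (14 higher, 3 lower, median 0.31, adjusted p = 0.000376), and their medians were -0.69, -0.38 and -0.13 in primary June, secondary October and primary October. The clock list was higher (12 of 19 higher, 2 lower, median 0.18, adjusted p = 0.00267), with CLOCK at 0.35. The ribosome was higher by its preset test (25 of 73 higher, 2 lower, median 0.05, adjusted p = 0.00429, and adjusted p = 0.625 with an estimated correlation), with medians of -0.18 and -0.06 in secondary and primary June and 0.35 and 0.09 in secondary and primary October.

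The members higher and lower in males, adjusted over the list alone, numbered 0 and 29 for cholesterol genes, 0 and 37 for cell cycle genes, 6 and 19 for proteases, 5 and 15 for immediate early genes, 1 and 7 for X-linked genes, 23 and 2 for the ribosome, 6 and 14 for Wnt ligands and 6 and 13 for inflammation, and the other lists named for this comparison kept their counts. With the 8 group means as single samples, 10 of the 6523 genes were called (7 higher and 3 lower in males), among them WNT5A, TNN and FADS2.

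In the single cell groups, with 3 males against 3 females, 5150 genes differed between the sexes in secondary June cells (2721 higher and 2429 lower in males), 5927 in primary June (3013 and 2914), 5277 in secondary October (2551 and 2726) and 4382 in primary October cells (2064 and 2318). With each library rescaled to a common total the split was 3563 higher and 1723 lower in secondary June and 1955 higher and 3437 lower in secondary October. In primary June it was 2513 higher and 3360 lower, and in primary October 2430 higher and 1944 lower. In secondary June the rescaled medians of the cell cycle and the ribosome were -0.04 and -0.12. Cholesterol and lipid synthesis was lower in males in each cell group, with 24, 24, 24 and 27 of 29 genes lower in that order (median -0.38, adjusted p = 1.74e-11 in secondary June, median -0.77, adjusted p = 1.12e-23 in primary October). Keratinocyte markers were higher in males in primary June (12 of 14 higher, 0 lower, median 0.85, adjusted p = 4.41e-08) and lower in secondary October (0 higher, 12 lower, median -1.59, adjusted p = 1.32e-11). There the mitochondrial share was 9.55 to 10.3% in males and 11.2 to 12.7% in females. Ribosomal protein genes were lower in males in secondary June (43 of 73 lower, 1 higher, median -0.18, adjusted p = 1.41e-09, and adjusted p = 0.288 with an estimated correlation) and higher in secondary October (70 higher, 0 lower, median 0.35, adjusted p = 3.12e-23, and adjusted p = 0.0591 with an estimated correlation). The interferon response was higher in males in secondary June (24 of 31 higher, 0 lower, median 0.43, adjusted p = 6.61e-10) and lower in primary October (1 higher, 20 lower, median -0.34, adjusted p = 8.56e-07). Immediate early genes were lower in the males of primary June (25 of 26 lower, 0 higher, median -0.66, adjusted p = 1.55e-17). The interaction of sex and month was called for 5203 genes, 354 of at least 2-fold, and that of sex and follicle type for 4628, 273 of at least 2-fold. Both keratinocyte (12 of 14 negative for month, 11 for follicle type) and interferon lists (23 of 31 negative for month, 24 positive for follicle type) passed in each (adjusted p = 5.59e-11 and 4.21e-12, and 3.1e-06 and 1.01e-10). Higher and lower members in males, adjusted over the list alone, numbered 1 and 44 for the ribosome in secondary June, 71 and 0 for the ribosome, 1 and 25 for cholesterol genes and 25 and 3 for the cell cycle in secondary October. In primary October they numbered 0 and 28 for cholesterol genes and 2 and 24 for the interferon response, and the other counts of list members given for these cell groups and interactions did not change.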

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

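The 3 tests on the secondary October male libraries and the counts within each sex were chosen after the result was seen. So were the count of splits that keep groups whole and the rescaling of each library to a common total. The other tests of this part were chosen before. Differences of effects between follicle types, months or sexes were each tested as an interaction. The interaction of follicle type and month was called for 6023 genes, that of sex and month for 5203 and that of sex and follicle type for 4628. The difference between secondary and primary cells differed between the sexes for 5381 genes in June and 3483 in October, and the change between the months for 4917 genes in secondary and 4799 in primary cells. Groups of 3 libraries are too small for a rule on outlying samples.

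Among the genes reported by name in the 4 comparisons of follicle type and month, 9 were called in opposite directions in the sexes. LEF1, a mediator of Wnt signals, differed between secondary and primary cells in June by 0.35 in females and -0.26 in males (SE 0.081 each; difference -0.61, adjusted p = 0.000165). NOG, an inhibitor of BMP signals, differed by 0.50 and -0.84 (SE 0.14; difference -1.34, adjusted p = 9.64e-06), RORA by -1.09 and 0.31 (SE 0.082; difference 1.41, adjusted p = 1.21e-09), and LAPTM5 by -4.32 and 0.78 (SE 0.093; difference 5.10, adjusted p = 1.55e-18). In October FGF10 differed by -0.52 in females and 0.35 in males (SE 0.084; difference 0.87, adjusted p = 5.87e-06), and KRT5 by 3.24 and -0.57 (SE 0.089; difference -3.81, adjusted p = 3.62e-16). From June to October WIF1 changed in primary cells by -1.50 and 0.70 (SE 0.13; difference 2.19, adjusted p = 1.1e-09), IGF1 by -0.80 and 1.91 (SE 0.095; difference 2.71, adjusted p = 1.86e-13) and ALDH1A1 by 0.34 and -2.52 (SE 0.094; difference -2.85, adjusted p = 7.47e-14).

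The 8 comparisons with enough libraries were each set against 100 splits of the same libraries, the real one included, of which 1, the real one, gave as many calls. The calls and the highest other split were as follows for secondary against primary cells in June (8079, 5817) and October (4116, 3483), the months in secondary (8206, 5103) and primary cells (7942, 5736), the interaction of follicle type and month (6023, 3989), males against females (6523, 2482), and the interactions of sex with month (5203, 1907) and with follicle type (4628, 1463). Whether chance can be excluded is not decided by these splits. Nearly all of them divided groups of 3 close libraries, which widens the spread, so the real split leads by design. Splits that keep the groups whole number 2 in each of the first 4 comparisons and 8 in each of the others, the real one included, too few for a share under 0.05. Of the other splits drawn, 1 in June (5381 calls) and 1 in October (3483) kept them whole and so exchanged the follicle types in one sex. Both counts equal those given above for genes whose difference between follicle types differed between the sexes. Splits that divided groups gave up to 5817 calls. Libraries were exchanged within pairs of groups, so a split can leave most libraries on their real side, and the cause of these counts was not tested. Males against females in one cell group allow only 10 splits, too few for a share under 0.05 (secondary June 5150 calls, highest other 2; primary June 5927, 0; secondary October 5277, 0; primary October 4382, 0).

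In the 4 comparisons of follicle type and month, between 4116 and 8206 of 13049 genes were called. Rescaling each library to a common total changed the number of calls in these 4 by a factor of at most 1.05. This does not decide whether the authors' scaling is a source, since totals run only from 959766 to 1045876 and rescaling could change the numbers little. Directions did move. The share of calls that were higher went from 51.1 to 59.3% and from 55.4 to 38% between the follicle types in June and October. It went from 46.2 to 40.1% and from 46.9 to 57.4% between the months in secondary and primary cells. That each group of 3 libraries differs on its own, whatever the factor, cannot be told apart from effects of the factors: the three-way term of month, follicle type and sex took 6.95% of the variance between group means, between the bounds set for and against it, beside 29.7% for month, 19.8% for follicle type and 16.7% for sex. The pairwise interactions took 10.4% (month by follicle type), 8.81% (month by sex) and 7.58% (follicle type by sex). Groups that differ on their own would add to these terms as well. Follicle type, month and sex stay open as biological differences that were not tested apart from the groups.

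The secondary October male libraries resembled primary ones: their mean r with primary October males was 0.992, and SOX2 stood at the primary level in them. The tables argue against a swap of the labels of these groups, since over 50 genes that separate the follicle types in the other 3 pairs of groups the difference kept its direction (median 0.351, quartiles 0.122 and 0.646, 42 genes the same way). The median in October females was 1.56, but the genes were chosen for a difference of at least 2-fold in the other 3 pairs. That choice included October females and left out October males, so the gap between these medians is partly fixed by it and does not measure a smaller difference in males. The tables also argue against libraries deposited under both names, since libraries differed 1.6 times as much between these groups as within them (median absolute log2 difference 0.125 against 0.0781). Cells of primary follicles in the libraries labelled secondary October male cannot be told apart from a smaller difference between follicle types in these samples: on a scale from 0 (other secondary groups) to 1 (primary groups) the 50 genes had a median position of 0.664 (quartiles 0.426 and 0.981), with SOX2 at 1.03 and ALDH1A1 at 0.120. These positions rest on the same 50 genes, whose choice used the other 3 pairs but not October males. A difference between the sexes in October stays open as well and was not tested apart from these libraries.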

How the results depend on the processing

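Rescaling each library to a common total, making the comparisons within each sex and taking the 8 group means as single samples were alternatives chosen after the result was seen. All others were chosen before. Every count of called genes stayed within 1.5 times its value with no filter, the stricter filter, a spread not estimated robustly, a pseudocount of 0.1, median-of-ratios factors, the compared groups alone (lowest against its own value: males against females in primary October, 2948 for 4382), rescaling (largest shift of the median of all genes -0.08), and each library left out in turn (7672 to 7984 and 3723 to 4414 for secondary against primary cells in June and October, 7778 to 7991 and 7529 to 8008 for the months in secondary and primary cells). Requiring a 2-fold change as well left 560, 97, 485 and 343 genes in these 4 comparisons, 477 for follicle type by month, 114 for males against females, 252, 530, 399 and 334 in secondary June, primary June, secondary October and primary October, 354 for sex by month and 273 for sex by follicle type, by construction. In males alone secondary against primary cells in October gave 2412 calls, and the cause was not tested. The 8 group means as single samples gave 341 calls for secondary against primary cells in June, 0 in October, 8 and 0 for the months in secondary and primary cells, 0 for follicle type by month and 10 for males against females (limma; 446, 2589 and 1181 genes at an unadjusted p under 0.05 where 0 were called). The 446 are a share under 0.05 of the 13049 tested genes, no more than unchanged genes would give. The fit of group means has fewer samples and takes the interactions with sex as spread. Of 813 named gene results, 813 were unchanged without robust estimation, 812 with median-of-ratios factors, 810 with no filter and 810 with a pseudocount of 0.1, under which LAPTM5 in follicle type by month reversed (-0.34, adjusted p = 0.229) and the cause was not tested. Requiring a 2-fold change as well ended 531 of the 813. With group means as single samples, 20 of 145 called named genes stayed called for secondary against primary cells in June and 0 of 131 in October. For the months, 3 of 141 in secondary and 0 of 139 in primary cells stayed called. So did 0 of 125 for follicle type by month and 3 of 123 for males against females. Leaving out 1 library changed 71 of 12678 results, 66 losing and 5 gaining a call. Of 360 list tests, 140 had passed with the preset correlation, and 63 of these 140 lost their call with an estimated correlation. With fry, which does not compare a list with other genes, 150 gained one, 1 lost it, and 4 reversed, the cause not tested: dermal sheath markers in secondary against primary October (adjusted p = 0.000158), matrix proteases in the months of secondary cells (0.0392), growth factors in males against females (0.0284) and BMP signalling in sex by month (0.0402). Planned count-based tests (DESeq2 and limma-voom) were not run because the values are not counts, and how far the unknown depth limits weakly expressed genes could not be measured.

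Replicate numbers did not clearly pair the libraries. Over 12 pairs of the same sex and month and the other follicle type, same-numbered libraries' deviations from their group means correlated with a median r of 0.0392 (-0.281 to 0.202). Libraries with other numbers had a median r of -0.023 (-0.401 to 0.512). Of 24 libraries, 12 correlated best with their own number among 3 candidates, so a weak pairing stays open. With a replicate block within sex, calls numbered 8125, 4216, 8283 and 8010 in the 4 comparisons of follicle type and month, 6121 for follicle type by month, 5289 for sex by month and 4724 for sex by follicle type. With the block within sex and month they numbered 7889, 3865, 5800 and 4325 for secondary against primary cells in June and October and the interactions of follicle type with month and sex, and with a number shared by the sexes 6710 for males against females and 5315, 6113, 5477 and 4574 in the 4 cell groups, so no count moved by over 1.5 times.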

Other observations

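No test of this part was chosen after the result was seen. Steroid, thyroid and retinoid signalling passed in none of the 6 main comparisons (secondary against primary June 8 of 24 higher and 13 lower, 9 and 14 adjusted over the list alone, median -0.21, adjusted p = 0.339; October 8 higher and 11 lower, median -0.10, adjusted p = 0.287). The retinaldehyde dehydrogenases divided the follicle types: where ALDH1A1 was lower in secondary cells, ALDH1A3 was higher, by 1.77 (SE 0.059) in June and 1.2 in October, with 16 ± 0.502 and 20.9 ± 1.29 (SD, n = 3) in secondary June females and males against 3.56 ± 0.475 and 6.08 ± 0.257 in primary ones. ALDH1A3 fell from June to October in both follicle types (-1.85 in secondary and -1.34 in primary cells). The vitamin D receptor VDR was lower in secondary cells (-1.08 in June, -0.84 in October) and higher in males (0.60), the oestrogen receptor ESR1 was lower in males (-0.78), and HSD11B1, which makes cortisol from cortisone, was higher in secondary June cells (1.45). The progesterone receptor PGR fell from June to October in secondary (-0.68) and primary cells (-1.32). Hedgehog signalling passed in none of them either (June 2 of 11 higher and 5 lower in secondary cells, median -0.10, adjusted p = 0.643), with GAS1 higher in secondary cells in both months (0.47 and 0.31).

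Adipocyte, Schwann cell and immune markers passed in none of the 6 main comparisons. In June 4 of 6 adipocyte markers were higher and 1 lower in secondary cells (median 0.49, adjusted p = 0.146). CIDEC, a lipid droplet protein, was higher (1.88, SE 0.10), at 6.05 ± 0.408 and 10.7 ± 1.72 (SD, n = 3) in secondary females and males against 1.65 ± 0.318 and 1.29 ± 0.433 in primary ones, and fell by October in secondary cells (-1.44). Of 5 Schwann cell markers, 3 were higher and 1 lower in June (3 and 2 adjusted over the list alone, median 0.27, adjusted p = 0.356), with the calcium-binding protein S100B at 0.89. For immune markers in June (2 of 8 higher, 2 lower) the median (0.11) and the mean and test (downward, adjusted p = 0.991) had opposite signs, and so had the medians in females (-0.10) and males (0.34). Of the 8 tested, LAPTM5 differed most, with 30.2 ± 3.47 in primary June females and 0.557, 1.03 and 0.18 in secondary females, secondary males and primary males. Of 4 tested melanocyte markers 2 were higher and 1 lower in secondary June cells, PMEL at 0.53. Of 4 endothelial markers 3 were higher and 1 lower, ERG at 0.66 and FLT1 at -0.89. Of 4 pericyte markers 1 was higher and 2 were lower, CSPG4 at 0.27. Among genes often studied in hair growth that were not tested, CORIN reached at most 0.34, FGF5 0.6 with 19 libraries listed at 0, the prolactin receptor PRLR 0.87, and the melatonin receptor MTNR1A 0.08 with 22 libraries listed at 0.

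Keratin genes were high in the secondary October female libraries, with KRT5 at 197 ± 9.45 and KRT14 at 77.5 ± 5 (SD, n = 3) against at most 27.9 and 29.1 in the other groups, although KRT8 was higher in primary October males (30.8 against 19.4). For the markers tested, the tables argue against a lower share of papilla cells that raises every other cell type alike, since 31 markers of 6 other cell types had a median difference of -0.0996 from the mean of the other 7 groups (quartiles -0.406 and 0.169). These were 4 of 11 melanocyte, 4 of 12 endothelial, 8 of 15 immune, 4 of 9 pericyte, 6 of 10 adipocyte and 5 of 10 Schwann cell markers. Cell types rare in every library could hardly show a rise. Keratinocytes among the cells are a candidate source: the other 12 tested keratinocyte markers, 9 of which had a mean of at least 1 in another group as well, differed by a median of 1.72 from the mean of the other 7 groups (quartiles 1.06 and 2.15, 11 of 12 higher, 9 of 12 highest in this group), and no sort that would remove such cells is given in the labels. These 12 markers belong to the list already given as higher in these libraries, so their median is no separate check of that result. What stays open is expression of keratins by the papilla cells themselves, and a difference between sexes, follicle types or months in the epithelium left on the papilla, neither of which was tested.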
